A study of Homo sapiens with 12 samples.

How the data were processed

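Whole-transcript arrays were read for 12 RNA samples of the cell lines BCWM.1 and MWCL-1, 3 untreated and 3 given NSC12 (6 µM, 12 h) per line. The titles of the samples spell BCWM.1 as BMCWM.1 and MWCL-1 as WMCL.1, which were taken as the same lines. The deposited table holds log2 values that the authors made with robust multi-array averaging (RMA) in oligo, per the submitters' processing notes. Versions, settings and genome build of that step are not given in the sources used here, and no coordinates were used. The table has 138745 probe sets. Of these, 36176 were given 1 gene symbol (25516 by Entrez identifier), 1119 matched several symbols and were left out of the gene tests, and 101450 were not named here. The named ones covered 33616 genes, of which 1576 had several probe sets, and each gene was represented by the probe set with the highest mean over all 12 arrays.

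Values were used as deposited. A gene was tested when at least 3 of 12 arrays exceeded the median of all values in the table (4.37), which left 24204 genes, 14726 of them protein-coding. Coding genes were called expressed when at least 3 arrays exceeded the 75th percentile of all values (5.89), which gave 11356. With limma 3.58.1 in R 4.3.3 (with statmod 1.5.0 and the package data.table, version 1.17.8), 1 linear model of 4 group means was fitted to all arrays, with 8 residual degrees of freedom and a prior of 5.345, and a moderated statistic was computed per gene, two-sided. Its contrasts were the NSC12 response in each line, their average, their difference and the untreated lines against each other. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. SE is the moderated standard error of the contrast and SD the spread of the 3 arrays.

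A set of 33 gene lists with 1034 genes was written from general knowledge before the data were examined, as were the samples' groups, the tests, the rule for named genes and all alternatives but those named as added. Lists were tested with camera at its preset correlation of 0.01, adjusted over the lists within a contrast, and also with an estimated correlation and with fry, which tests whether a list's genes move on balance one way. Each list's median was set beside those of 10000 random coding lists matched in 20 bins of expression, with the central 95% as the range. The lists were mitosis, DNA replication and E2F targets, histones, MYC targets, respiratory chain, glycolysis, cholesterol and fatty acid synthesis, LXR targets, interferon response, MHC class II, B-cell identity, B-cell receptor signalling, plasma cell, IgM and immunoglobulin constant genes, MYD88 and Toll-like receptor signalling, FGF ligands and receptors, NF-kB, JAK-STAT3, MAPK feedback, ATF4, unfolded protein response, NRF2, heat shock, hypoxia, p53, BCL2 family, autophagy, metallothioneins, chemokine receptors and markers of T and NK cells, monocytes and fibroblasts.

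Named genes were the measured members of FGFR1, FGFR2, FGFR3, FGFR4, FGF2, MYD88, BTK and MYC (IRAK1 and IRAK4 were not analysed here). They also included the 10 largest rises and falls of coding genes per line among called genes whose treated and untreated values did not overlap, which chance gives to 10% of genes with 3 against 3 arrays. Up to 4 members of each list with the smallest p in the average response were added, with the 5 largest called differences between the lines in each direction and the 10 largest between the untreated lines. The gene families among the other observations were chosen after their values were seen. Other, dimmer probe sets of LIPA (-0.04 and 0.27), BANK1 (0.08), SQSTM1 (0.03), SYK (-0.24) and GNAQ (-0.60) had NSC12 responses in BCWM.1 nearer 0 than the probe sets used. In MWCL-1 the other probe set of BANK1 (0.44 against -0.64) and 1 of LIPA (0.56 against -0.49) had the opposite sign. These probe sets were not compared singly between the untreated lines.

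Alternatives were centring each array on its median, quantile normalization again, no filter, the 75th percentile as filter, the mean of a gene's probe sets, all probe sets, a trended and robust prior, array weights, only the 6 arrays of a comparison, a replicate block, each array left out in turn, a 2-fold limit, adjusted p under 0.01, the estimated correlation and fry. Centring on the expressed coding genes and scaling to the 4 poly-A controls were added after the data were seen. A result was taken as unaltered when its direction and side of the threshold were the same or when neither value passed, a count when within 1.5 times, and a correlation when within 0.1. The steps were tested on simulated data with 24204 genes, where 22.4%, 80.6% and 100% of genes changed by log2 0.5, 1 and 2 were recovered in BCWM.1 and 8 of 143 calls were unchanged genes. That simulation changed 200 genes, in treated BCWM.1 alone and with independent noise. In the real BCWM.1 response 46.7% of genes were called, so these shares are not the recovery of the real tests. XIST, TSIX and genes of the Y chromosome were not named, and the 2995 control probe sets were used only to compare arrays, apart from the scaling to the 4 poly-A controls.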

Results

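Gene expression was measured on 12 whole-transcript arrays in BCWM.1 and MWCL-1, a pair of B-lineage lines derived from Waldenström macroglobulinemia, a lymphoma of lymphoplasmacytic cells that secrete IgM. Each line was left untreated or given NSC12, a small molecule that traps fibroblast growth factors (FGF), at 6 µM for 12 h, with 3 arrays in each of the 4 groups. The title of the study links FGF signalling to MYD88, the adaptor of Toll-like and interleukin-1 receptors that is recurrently mutated in this disease. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values may measure technical spread alone. Pearson's r between arrays of a group, across genes, which are not independent replicates, lay between 0.980 and 0.989. The number of arrays limits the precision of every value.

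The first comparison asked which transcripts changed in BCWM.1 after NSC12. MYD88 mRNA fell 4.79-fold (log2 -2.26, SE 0.14, n = 3 arrays per group, adjusted p = 6.1e-08), from a signal of 9.85 ± 0.04 (SD, log2) to 7.60 ± 0.12. BTK, the tyrosine kinase that acts below the B-cell receptor and MYD88, fell 3.53-fold (log2 -1.82, SE 0.12, adjusted p = 6.93e-08). MYC, the transcription factor of growth and proliferation, rose 1.88-fold (log2 0.91, SE 0.11, adjusted p = 9.71e-06), but stood at -0.45 when arrays were scaled to their poly-A controls. Genes of the FGF axis changed less. FGFR4 rose by 0.31 on the log2 scale (SE 0.12, adjusted p = 0.0499), whereas FGF2 dropped by 0.38 (SE 0.13, adjusted p = 0.0309). FGFR1 (log2 0.22), FGFR2 (0.16) and FGFR3 (-0.16) did not pass the test as deposited, but this depended on the scaling. FGFR1 (0.78, adjusted p = 0.000329) and FGFR2 (0.72, 0.00976) were called up with centring on expressed coding genes, and FGFR1 (-1.13, 8.14e-06), FGFR2 (-1.20, 4.62e-06) and FGFR3 (-1.52, 3.88e-08) were called down with scaling to the poly-A controls, where the highest values over the alternatives were 0.704, 0.889 and 0.945. The FGFR4 call ended without untreated replicate 2 (log2 0.22, adjusted p = 0.194), untreated replicate 3 (0.29, 0.122), NSC12 replicate 1 (0.31, 0.0770) or NSC12 replicate 3 (0.23, 0.179), and the FGF2 call without untreated replicate 2 (-0.29, 0.132), NSC12 replicate 2 (-0.31, 0.115) or NSC12 replicate 3 (-0.40, 0.0532), while FGFR1 passed without untreated replicate 2 (0.39, 0.0341). A replicate block (adjusted p = 0.0834 and 0.0620) and a fit of only the 6 BCWM.1 arrays (0.133 and 0.0595) ended the calls of FGFR4 and FGF2, and that of FGFR4 also ended with median centring (0.25, 0.0992) or no filter (0.0754). Over 17 alternatives the adjusted p ranged from 4.07e-05 to 0.194 for FGFR4 and from 1.29e-09 to 0.222 for FGF2. The lowest of both came with scaling to the poly-A controls, where FGFR4 stood at -1.05, and the highest of FGF2 with centring on expressed coding genes, where FGF2 stood at 0.17.

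**Figure D1:**
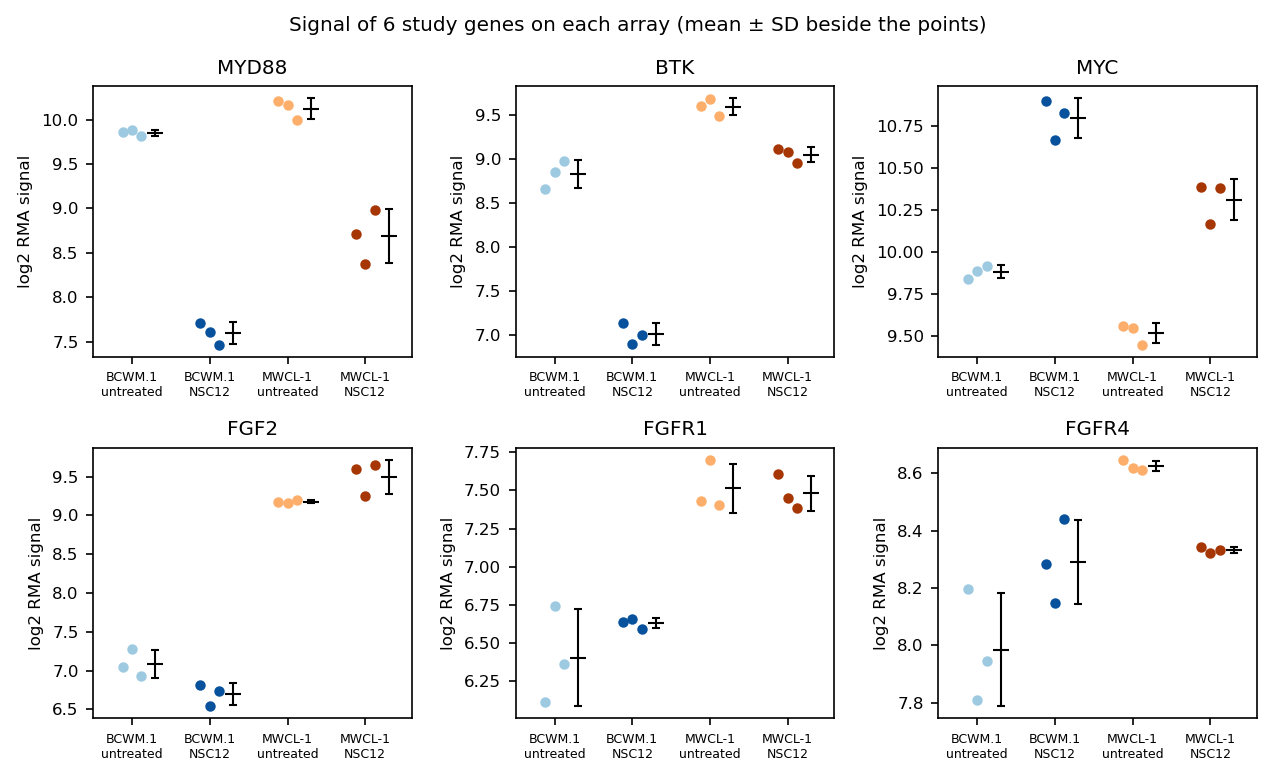
Log2 RMA signal of 6 study genes on each of the 12 arrays, in 4 groups of 3 (points), with the mean and SD of each group beside the points. MYD88 lay at 9.85 in untreated BCWM.1 and 7.60 after NSC12, and at 10.12 and 8.69 in MWCL-1, while MYC rose in both lines.

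The largest rise of a coding gene in BCWM.1 was that of KCND2, a voltage-gated potassium channel, at 20.4-fold (log2 4.35, SE 0.11). CREBRF, a regulator of CREB3 that responds to stress, rose 13.3-fold and the AP-1 subunit JUN 10.3-fold. The stress-induced transcription factor ATF3 rose 4.89-fold, the cell-cycle repressor HBP1 5.33-fold and the coagulation inhibitor TFPI 5.06-fold. CSRNP1 and ZBTB10 rose 7.67-fold and 7.21-fold. A pair of olfactory receptor genes, OR5K4 and OR5H6, rose by log2 2.87 and 2.73 from signals of 4.24, under the filter of 4.37 for dim genes, and 4.62, close to it, so that background limits the size of these rises. The largest falls were those of PBK (7.93-fold), a mitotic kinase, CLECL1 (7.28-fold, to a signal of 4.19 under the filter), the DNA exonuclease EXO1 (7.18-fold), FAM111B (7.13-fold), the centromere protein CENPI (7.03-fold) and the lysosomal lipase LIPA (7.02-fold). They were followed by the sterol synthesis enzyme ACAT2 (6.98-fold), the cyclin CCNE2 (6.88-fold), the spindle protein SPAG5 (6.83-fold) and TLR7, an endosomal receptor of single-stranded RNA (6.82-fold).

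Proliferation genes fell as a body in BCWM.1. All 55 measured genes of the mitosis list fell (median log2 -1.82, camera adjusted p = 1.18e-23 and adjusted p = 0.174 with an estimated correlation). Examples were CDK1 (-2.10) and AURKA (-1.93). All 49 of the DNA replication and E2F list fell (median -1.79, adjusted p = 3.08e-20 and adjusted p = 0.186 with an estimated correlation). Examples were the replication clamp PCNA (-1.99) and RRM2 (-2.16), which makes deoxyribonucleotides. Of 23 cholesterol synthesis genes, 21 fell and 2 did not pass (median -1.26, adjusted p = 2e-08 and adjusted p = 0.174 with an estimated correlation). FDPS dropped by 2.01 and DHCR7, the last enzyme of the pathway, by 1.54. Fatty acid synthesis had 11 of 15 genes lower and 4 not called (median -1.01, adjusted p = 0.00091 and adjusted p = 0.234 with an estimated correlation). SCD stood at -1.65, ACLY at -1.88 and ELOVL6 at -2.40.

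Energy and growth genes were lower too. In the nuclear-encoded respiratory chain 45 of 50 genes fell and 5 did not pass (median -0.84, adjusted p = 3.14e-10 and adjusted p = 0.234 with an estimated correlation). Examples were ATP5MC1 (-1.32) and NDUFS5 (-1.12). MYC targets and ribosome biogenesis had 35 of 39 lower and 4 not called (median -0.85, adjusted p = 2.05e-08 and adjusted p = 0.234 with an estimated correlation). PAICS stood at -1.20 and TFB2M at -1.53, although MYC itself rose. Glycolysis had 15 of 20 lower and 5 not called (median -0.74, adjusted p = 0.0013 and adjusted p = 0.305 with an estimated correlation). LDHA stood at -1.09 and PGAM1 at -1.48. Of 47 replication-dependent histone genes, 33 fell and 14 did not pass (median -0.63, adjusted p = 6.32e-06 and adjusted p = 0.305 with an estimated correlation), for example H2BC14 (-1.73) and H1-5 (-1.33). These falls stood against a general one: random lists of coding genes matched for expression had median changes between -0.67 and -0.58. The medians for histones and glycolysis lay at percentiles 33.8 and 21.6 of these lists, that of the respiratory chain at 4.8 and that of MYC targets at 2.65, all inside the central 95%. Mitosis, E2F and cholesterol synthesis lay at percentile 0.

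Immune signalling was mixed in BCWM.1. Of 37 interferon response genes, 26 fell, 5 rose and 6 did not pass (median -0.70, adjusted p = 0.00461 and adjusted p = 0.489 with an estimated correlation), and the guanylate-binding protein GBP1 and the antiviral protein IFIT1 were lower by log2 -2.48 and -1.79. B-cell receptor signalling had 18 of 26 genes lower, 2 higher and 6 not called (median -0.55, adjusted p = 0.0121 and adjusted p = 0.335 with an estimated correlation, and a median of 0.01 when arrays were centred on expressed coding genes), with PRKCB at -1.26, SYK at -0.97 and the inhibitory Fc receptor FCGR2B at -1.29. The unfolded protein response list, which holds targets of XBP1 and ATF6, had 26 of 39 lower, 5 higher and 8 not called (median -0.61, adjusted p = 0.024 and adjusted p = 0.561 with an estimated correlation). Its call ended without NSC12 replicate 2 (adjusted p = 0.0503). As deposited, the disulfide isomerase PDIA6 fell (log2 -1.55), and the co-chaperone DNAJB9 (1.73) and the stress sensor ERN1 (0.63) rose, but scaled to the poly-A controls DNAJB9 stood at 0.37 (adjusted p = 0.109, the highest of 17 alternatives) and ERN1 at -0.73. In the NRF2 oxidative stress list 15 of 28 fell, 3 rose and 10 did not pass (median -0.39, or 0.17 when centred on expressed coding genes, adjusted p = 0.031 and adjusted p = 0.391 with an estimated correlation). PGD stood at -1.15 and the autophagy receptor SQSTM1 at 0.68, or 0.36 and not called with the mean of its probe sets (adjusted p = 0.0835, the highest of 17 alternatives). None of these 4 calls held with quantile normalization again (adjusted p = 0.0716 for interferon, 0.166 for B-cell receptor signalling, 0.363 for the unfolded protein response and 0.244 for NRF2) or with the stricter filter (0.096, 0.096, 0.223 and 0.223). Over 19 alternatives the highest values were those with an estimated correlation. The medians of these 4 lists lay at percentiles 31.0, 59.5, 54.9 and 89.2 of the matched random lists, inside their central 95%.

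Several stress and signalling groups were called higher by camera in BCWM.1, with medians at percentile 99.88 or above of the matched random lists. Metallothioneins, which bind zinc, had 8 of 9 measured genes higher and 1 lower (median 1.96, adjusted p = 4.49e-10 and adjusted p = 0.0188 with an estimated correlation), and MT1F and MT1G rose by 2.26 and 1.96. MAPK feedback and immediate early genes had 18 of 36 higher, 5 lower and 13 not called (median 0.47, but -0.89 when scaled to the poly-A controls, adjusted p = 2.74e-08 and adjusted p = 0.174 with an estimated correlation). Examples were the phosphatases DUSP4 (1.87) and DUSP2 (1.84). NF-kB targets had 13 of 28 higher, 2 lower and 13 not called (median 0.27, but -1.09 when scaled to the poly-A controls, adjusted p = 5.02e-06 and adjusted p = 0.234 with an estimated correlation). Examples were the inhibitor NFKBIA (1.29), TNFAIP3 (0.88) and REL (0.78), which stood at -0.069, -0.48 and -0.58 when so scaled. ATF4 and amino acid response genes had 14 of 43 higher, 5 lower and 24 not called (median 0.14, but -1.22 when scaled to the poly-A controls, adjusted p = 0.000184 and adjusted p = 0.335 with an estimated correlation). PPP1R15A stood at 1.93, the amino acid transporter chain SLC3A2 at 1.24 and CTH at 1.39, or 0.026 and not called when scaled to the poly-A controls (adjusted p = 0.908). FGF ligands and receptors had 3 of 23 genes higher, 1 lower and 19 not called (median 0.16, but -1.20 when scaled to the poly-A controls, adjusted p = 0.0158 and adjusted p = 0.249 with an estimated correlation), and FGF8 and FGF9 rose by 0.49 and 0.53. Of all 24204 tested genes 2972 were called up, a like share. Camera ranks a list against all other genes, and the median change of all tested genes was -0.15, so this call need not mean a rise. The FGF call ended with quantile normalization again (adjusted p = 0.0505) or scaling to the poly-A controls (0.0917).

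The remaining lists did not pass in BCWM.1 as deposited, although some did under alternatives. MYD88 and Toll-like receptor signalling had 6 of 29 genes higher and 11 lower (adjusted p = 0.875), with a median of -0.06 and a camera direction of up: TLR10 fell (-1.81) and IRAK2 rose (1.49, but 0.13 and adjusted p = 0.580 when scaled to the poly-A controls), and IRAK1 and IRAK4 were not analysed here. Plasma cell genes had 4 of 21 higher and 14 lower (adjusted p = 0.0865), with the master regulator PRDM1 at -1.85, the BAFF and APRIL receptor TNFRSF17 at -2.01 and JCHAIN at -2.15. MHC class II presentation had 8 of 13 lower and 0 higher (adjusted p = 0.0963), the BCL2 family 5 of 19 higher and 8 lower (adjusted p = 0.736), with the pro-apoptotic BCL2L11 at 1.49 (0.13 and adjusted p = 0.575 when so scaled) and PMAIP1 at 0.83 (-0.53), and JAK-STAT3 and cytokine signalling 9 of 24 higher and 7 lower (adjusted p = 0.0604). JAK-STAT3 signalling passed without untreated replicate 2 (adjusted p = 0.0443), with quantile normalization again (0.0349), the stricter filter (0.0359), the mean of probe sets (0.0291), array weights (0.0498) and scaling to the poly-A controls (0.0424). Plasma cell genes passed without NSC12 replicate 1 (0.04998), with no filter (0.0123), with centring on expressed coding genes (0.0372) and with scaling to the poly-A controls (0.0478), and MHC class II with no filter (0.0254). Their highest values over 19 alternatives were 0.402, 0.561 and 0.693. LXR targets had 2 of 9 higher and 1 lower (adjusted p = 0.254), with ABCA1 at 0.99 and ABCG1 at 0.53, both cholesterol exporters, and LPCAT3 at -1.84. Scaled to the poly-A controls, ABCA1 stood at -0.37 and ABCG1 at -0.83. Higher and lower counts were 6 and 8 of 25 for B-cell identity (adjusted p = 0.718), 2 and 12 of 21 for heat shock (0.135), 0 and 4 of 8 for IgM and immunoglobulin constant genes (0.374), 4 and 14 of 30 for p53 targets (0.571), 5 and 22 of 48 for autophagy and lysosome (0.571), 4 and 13 of 25 for chemokine receptors and adhesion (0.736) and 4 and 12 of 23 for hypoxia (0.767). Markers of other cell types also gave no call, with 1 and 3 of 15 for T and NK cells (0.399), 2 and 1 of 15 for monocytes and macrophages (0.401) and 1 and 4 of 15 for fibroblasts and stroma (0.736). Camera, which ranks a list against all other genes, gave an upward direction beside a negative median for B-cell identity (-0.10), the BCL2 family (-0.13) and monocytes (-0.11), and T and NK cell markers had a median of 0.10 and a mean of -0.11. Adjusted over the list alone, counts of higher and lower genes differed from these for the respiratory chain (0 and 47), NF-kB (15 and 2), histones (0 and 35), glycolysis (0 and 16), interferon (6 and 26), FGF (2 and 0), autophagy (6 and 23) and monocytes (1 and 1).

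In all, 11293 of 24204 tested genes changed in BCWM.1, 2972 up and 8321 down, of which 653 and 3048 changed at least 2-fold. The 11356 expressed coding genes had a median change of -0.46, with 6288 of them lower and 831 higher. On the same arrays the poly-A controls, foreign RNAs added to each sample, rose by 1.36 (SE 0.16, exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The balance of rises and falls changed with the scaling: 12349 genes rose and 3843 fell with arrays centred on expressed coding genes (median of all genes 0.41), and 128 rose and 23384 fell with arrays scaled to the poly-A controls (-1.51), against a median of -0.15 as deposited.

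**Figure D2:**
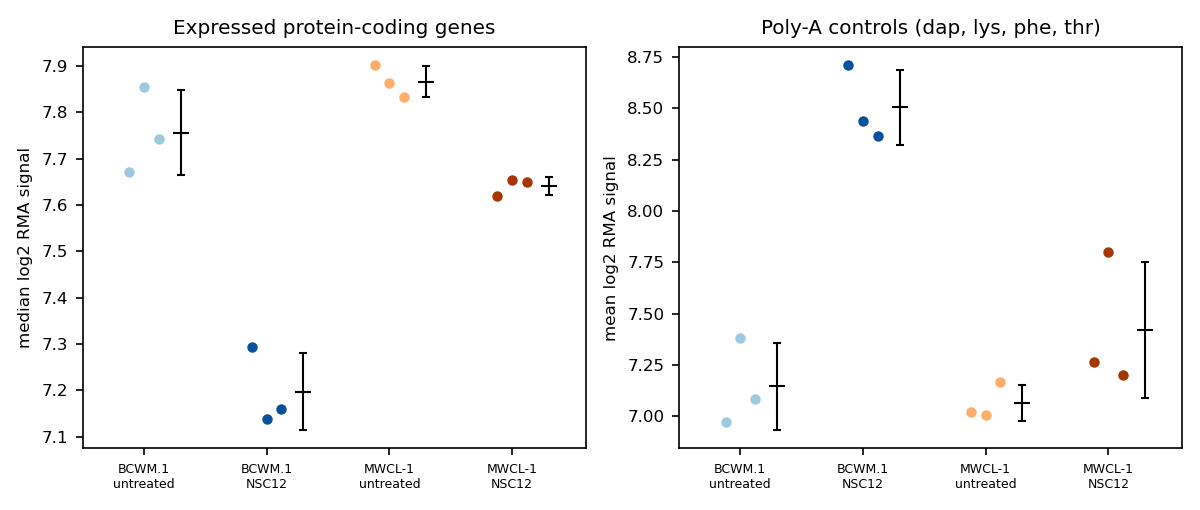
Left, median log2 RMA signal of 11356 expressed coding genes on each array; right, mean log2 RMA signal of the poly-A controls. Points are the 12 arrays in 4 groups of 3, with mean and SD. The median signal of coding genes fell by 0.56 in BCWM.1 and by 0.23 in MWCL-1 while the poly-A controls rose by 1.36 and 0.36.

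The second comparison asked the same of MWCL-1. MYD88 fell 2.70-fold (log2 -1.43, SE 0.14, n = 3 arrays per group, adjusted p = 6.81e-06), from 10.12 ± 0.12 to 8.69 ± 0.30, and BTK fell 1.46-fold (log2 -0.54, SE 0.12, adjusted p = 0.0029). MYC rose 1.73-fold (log2 0.79, SE 0.11, adjusted p = 8.86e-05). None of the receptors FGFR1 (log2 -0.03), FGFR2 (0.25), FGFR3 (-0.15) and FGFR4 (-0.29) passed as deposited, nor did FGF2 (0.32). FGFR4 passed with the stricter filter (adjusted p = 0.0492), array weights (0.0357), only the 6 MWCL-1 arrays (0.0348) and scaling to the poly-A controls (-0.65, 0.0242), and otherwise reached 0.731. FGF2 passed with quantile normalization again (0.49, 0.0125), array weights (0.37, 0.0203), centring on expressed coding genes (0.55, 0.00445) and without NSC12 replicate 2 (0.45, 0.0257), and otherwise reached 0.909. The largest rises were those of the heme-degrading enzyme HMOX1 (11.1-fold, log2 3.47, SE 0.15), the mitochondrial folate enzyme ALDH1L2 (11.1-fold, log2 3.47, SE 0.15), the chemokine CXCL8 (8.81-fold), ATF3 (8.37-fold), the cytokine IL6 (7.97-fold), the cysteine synthesis enzyme CTH (7.03-fold), RGCC (6.90-fold, from a signal under the filter for dim genes), TRIB3 (6.67-fold), MT1F (6.10-fold) and EIF4EBP1 (5.66-fold), which restrains translation. CD180, a surface relative of the Toll-like receptors, fell from a signal of 9.08 to 3.88 (log2 -5.20, SE 0.18), under the filter of 4.37 for dim genes, so that background limits the size of this fall. The other largest falls were those of the fatty acid transporter SLC27A2 (8.07-fold), IFIT1 (7.80-fold), GAPT (7.69-fold), MPEG1 (7.57-fold), CCNE2 (7.55-fold), FAM111B (7.14-fold), TMEM19 (7.13-fold), TMT1A (5.43-fold) and ACAT2 (5.39-fold).

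Amino acid and protein folding stress genes rose together in MWCL-1. Of 43 ATF4 and amino acid response genes, 36 rose, 1 fell and 6 did not pass (median log2 0.99, adjusted p = 2.69e-29 and adjusted p = 0.0274 with an estimated correlation). TRIB3 stood at 2.74, the cystine transporter SLC7A11 at 1.88, SLC3A2 at 1.92 and PPP1R15A at 1.73. The unfolded protein response had 28 of 39 higher, 0 lower and 11 not called (median 0.51, adjusted p = 7.99e-16 and adjusted p = 0.0742 with an estimated correlation). Examples were DNAJB9 (2.13), the COPII coat gene SEC24D (1.62) and ERN1 (1.37), while PDIA6 stood at -0.18 and did not pass. In the NRF2 list 10 of 28 rose, 8 fell and 10 did not pass (median 0.16, but -0.19 when scaled to the poly-A controls, adjusted p = 0.0282 and adjusted p = 0.281 with an estimated correlation), led by HMOX1 and SLC7A11. The NRF2 call ended with no filter (adjusted p = 0.0514). Metallothioneins had 8 of 9 higher and 1 not called (median 1.31, adjusted p = 9.52e-11 and adjusted p = 0.0168 with an estimated correlation). MAPK feedback and immediate early genes had 25 of 36 higher, 1 lower and 10 not called (median 0.62, adjusted p = 1.41e-13 and adjusted p = 0.0433 with an estimated correlation). JUN stood at 2.06, DUSP4 at 1.66 and DUSP2 at 1.05. NF-kB targets had 17 of 28 higher, 1 lower and 10 not called (median 0.48, adjusted p = 2.86e-08 and adjusted p = 0.084 with an estimated correlation). TNFAIP3 stood at 0.84 and REL at 0.80, or at 0.48 and 0.44 and not called when scaled to the poly-A controls. JAK-STAT3 and cytokine signalling had 7 of 24 higher, 3 lower and 14 not called (median 0.19, but -0.17 when scaled to the poly-A controls, adjusted p = 0.0127 and adjusted p = 0.248 with an estimated correlation). BCL6 stood at 0.91, and IL6 was among the members.

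The groups that fell in MWCL-1 covered proliferation, lipid synthesis, energy and immune genes. Mitosis had 54 of 55 lower and 1 not called (median -1.35, adjusted p = 3.1e-31 and adjusted p = 0.0724 with an estimated correlation). CDK1 stood at -2.02. DNA replication and E2F targets had 46 of 49 lower and 3 not called (median -1.09, adjusted p = 1.09e-23 and adjusted p = 0.0744 with an estimated correlation). PCNA stood at -1.88. Cholesterol synthesis had 20 of 23 lower and 3 not called (median -1.22, adjusted p = 1.02e-14 and adjusted p = 0.0413 with an estimated correlation). DHCR7 stood at -2.25 and FDPS at -1.62. Fatty acid synthesis had 8 of 15 lower, 1 higher and 6 not called (median -0.52, adjusted p = 0.0127 and adjusted p = 0.257 with an estimated correlation). SCD stood at -1.44. The respiratory chain had 42 of 50 lower and 8 not called (median -0.71, adjusted p = 1.44e-17 and adjusted p = 0.0744 with an estimated correlation). Glycolysis had 13 of 20 lower, 1 higher and 6 not called (median -0.67, adjusted p = 2.49e-05 and adjusted p = 0.147 with an estimated correlation). LDHA stood at -1.64. MYC targets had 24 of 39 lower, 2 higher and 13 not called (median -0.45, adjusted p = 3.29e-06 and adjusted p = 0.248 with an estimated correlation). Histones had 23 of 47 lower, 5 higher and 19 not called (median -0.33, adjusted p = 0.00467 and adjusted p = 0.411 with an estimated correlation), and their call ended with scaling to the poly-A controls (adjusted p = 0.0521).

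Of 37 interferon response genes in MWCL-1, 29 fell, 1 rose and 7 did not pass (median -1.08, adjusted p = 9.06e-14 and adjusted p = 0.0744 with an estimated correlation). IFIT1 stood at -2.96, IFI6 at -2.12, GBP1 at -2.12 and MX1 at -1.68. MHC class II presentation had 11 of 13 lower and 2 not called (median -0.64, adjusted p = 1.16e-06 and adjusted p = 0.0841 with an estimated correlation). Examples were the peptide exchange factors HLA-DMA (-1.37) and HLA-DMB (-1.04) and HLA-DPB1 (-1.21). B-cell identity had 16 of 25 lower, 2 higher and 7 not called (median -0.51, adjusted p = 0.00791 and adjusted p = 0.189 with an estimated correlation). STAP1 stood at -1.05 and FCRLA at -0.73. B-cell receptor signalling had 10 of 26 lower, 1 higher and 15 not called (median -0.24, adjusted p = 0.0127 and adjusted p = 0.269 with an estimated correlation). SYK stood at -1.40. The medians for histones and B-cell receptor signalling lay inside the central 95% of matched random lists, at percentiles 15 and 44.3, and those of the other 17 called lists lay outside it.

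The other lists gave no call in MWCL-1 as deposited, although some did under alternatives. IgM and immunoglobulin constant genes passed with no filter (adjusted p = 0.0494) and by fry (0.000261). LXR targets passed with scaling to the poly-A controls (0.0236) and by fry (0.000116). Chemokine receptors (0.00157), heat shock (0.00329), fibroblast and stromal markers (0.00623) and plasma cell genes (0.0476) passed by fry. MYD88 and Toll-like receptor signalling had 4 of 29 higher and 7 lower (adjusted p = 0.985), with TLR7 at -1.27, TLR10 at -1.28 and IRAK2 at 1.95. Plasma cell genes had 7 of 21 higher and 6 lower (adjusted p = 0.999), with PRDM1 at -1.64, TNFRSF17 at -1.94 and JCHAIN at -2.14. LXR targets had 2 of 9 higher and 1 lower (adjusted p = 0.132), with ABCA1 at 2.15, ABCG1 at 2.05 and LPCAT3 at -1.17. FGF ligands and receptors had 2 of 23 higher and 0 lower (adjusted p = 0.0741), and passed without untreated replicate 3 (adjusted p = 0.0363) or NSC12 replicate 3 (0.0452). Higher and lower counts were 0 and 3 of 8 for IgM and immunoglobulin constant genes (adjusted p = 0.129), 2 and 6 of 25 for chemokine receptors and adhesion (0.163), 3 and 8 of 21 for heat shock (0.428), 5 and 5 of 23 for hypoxia (0.428), 6 and 8 of 30 for p53 targets (0.922), 2 and 5 of 19 for the BCL2 family (0.922), 6 and 12 of 48 for autophagy and lysosome (0.983), 0 and 3 of 15 for fibroblasts and stroma (0.724), and 1 and 1 of 15 for both T and NK cells (0.824) and monocytes and macrophages (0.824). Camera gave an upward direction beside a negative median for hypoxia (-0.04, with a mean of 0.05), p53 targets (-0.16), autophagy (-0.12), T and NK cells (-0.02) and monocytes (-0.04). Adjusted over the list alone, counts of higher and lower genes differed for mitosis (0 and 55), E2F targets (0 and 47), the respiratory chain (0 and 46), the unfolded protein response (29 and 0), interferon (3 and 32), MHC class II (0 and 12), MYC targets (2 and 25), glycolysis (2 and 14), histones (5 and 26), B-cell receptor (1 and 11), JAK-STAT3 (8 and 4), NRF2 (11 and 8), FGF (0 and 0), heat shock (4 and 8), p53 (9 and 13), MYD88 (4 and 8), plasma cell (7 and 7), T and NK cells (0 and 1) and monocytes (0 and 1).

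In MWCL-1 7372 of 24204 genes changed, 2428 up and 4944 down, of which 571 and 885 changed at least 2-fold. Expressed coding genes had a median change of -0.17, with 3542 lower and 997 higher, and the poly-A controls rose by 0.36 (SE 0.20, exact permutation p = 0.1). Centred on expressed coding genes, 5235 genes rose and 2932 fell (median of all genes 0.16, against -0.06 as deposited), and scaled to the poly-A controls 675 rose and 8643 fell (-0.42), with MYC at 0.44 and no longer called (adjusted p = 0.127, with a range of 1.44e-08 to 0.127 over 17 alternatives).

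**Figure D3:**
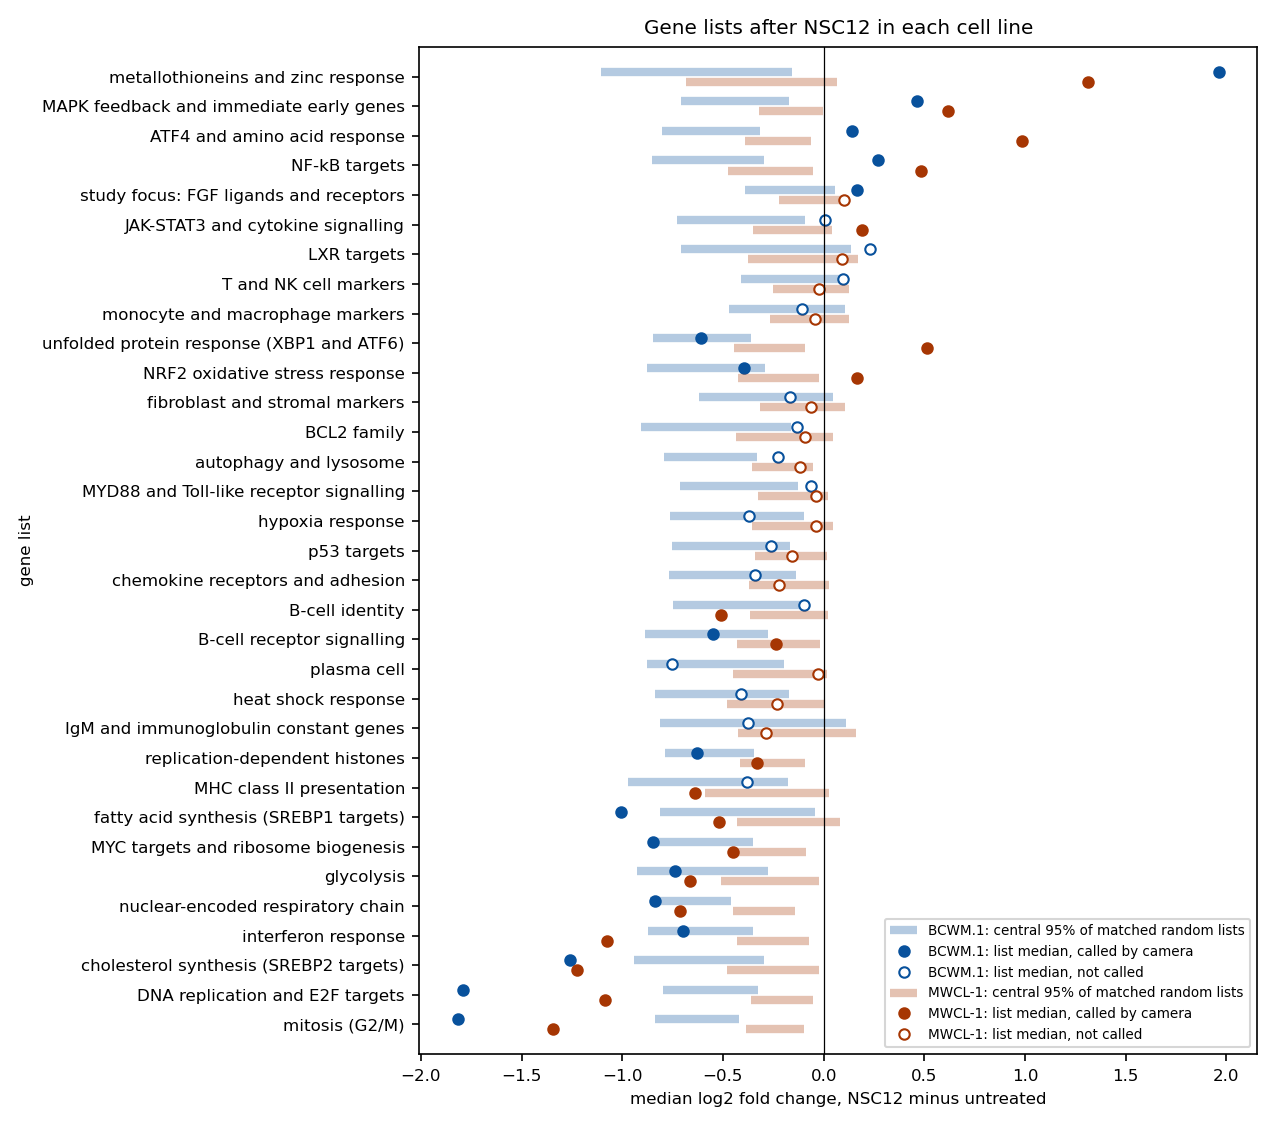
Median log2 fold change of each of 33 gene lists after NSC12, in BCWM.1 (blue) and MWCL-1 (brown), with filled points for lists called by camera and open points for lists not called; bars span the central 95% of medians of 10000 random coding lists of matched expression. Values are as deposited; scaled to the poly-A controls, the BCWM.1 medians for MAPK, NF-kB, ATF4 and FGF genes were below 0, as were those for LXR, JAK-STAT3 and T and NK cell genes. Centred on expressed coding genes, the BCWM.1 medians were above 0 for NRF2, B-cell receptor signalling, MHC class II, B-cell identity, immunoglobulin constant, MYD88, BCL2 family, autophagy, chemokine receptor, heat shock, hypoxia, p53, fibroblast and monocyte genes. In MWCL-1 those for NRF2, JAK-STAT3, LXR and FGF genes were below 0 with the first scaling, and several lists not called were above 0 with the second. The unfolded protein response stood at -0.61 in BCWM.1 and 0.51 in MWCL-1.

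The responses of the lines were then compared directly, as the BCWM.1 change minus the MWCL-1 change. The lines differed most in folding, amino acid and oxidative stress genes. Of 39 unfolded protein response genes, 33 had a lower response in BCWM.1 and 0 a higher one (median difference -1.19, adjusted p = 5.37e-22 and adjusted p = 0.123 with an estimated correlation). Examples were PDIA6 (-1.36), SEC24D (-1.19) and ERN1 (-0.74). The ATF4 list had 30 of 43 lower and 0 higher (median -0.77, adjusted p = 8.15e-15 and adjusted p = 0.123 with an estimated correlation). ALDH1L2 stood at -3.23, TRIB3 at -1.92, SLC7A11 at -1.67, CTH at -1.43 and SLC3A2 at -0.68. The NRF2 list had 15 of 28 lower and 0 higher (median -0.58, adjusted p = 1.91e-07 and adjusted p = 0.123 with an estimated correlation), led by HMOX1 (-3.53, SE 0.21), whose signal was 7.53 and 7.47 without and with NSC12 in BCWM.1 and 7.20 and 10.67 in MWCL-1. The cell-cycle regulator RGCC (-3.18), IL6 (-3.03) and IL1A (-2.81) were also among the largest differences, but the JAK-STAT3 and cytokine list was not called (3 of 24 higher and 3 lower, adjusted p = 0.621).

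MYD88 fell more in BCWM.1 as deposited (difference -0.83, SE 0.20, adjusted p = 0.0123). Centred on expressed coding genes, it stood at -0.49 and was not called (adjusted p = 0.0907, the highest of a range from 1.24e-05). BTK fell more in BCWM.1 (-1.28, SE 0.17, adjusted p = 0.000262). For MYC no difference was called (0.12, adjusted p = 0.66). FGFR4 (0.60, adjusted p = 0.0251, but -0.40 and adjusted p = 0.239 when scaled to the poly-A controls, over a range from 0.00673) and FGF2 (-0.71, adjusted p = 0.0201, but -0.37 and not called when centred on expressed coding genes, adjusted p = 0.139, the highest of a range from 2.31e-05) differed. FGFR1 (0.26), FGFR2 (-0.09) and FGFR3 (-0.01) did not pass. The largest differences in the other direction were those of CD180 (4.11), the microRNA gene MIR8061 (3.94), IGHV3OR16-6 (3.05), GAPT (3.04) and IGKV1D-39 (2.94). CD180, IGHV3OR16-6, GAPT and IGKV1D-39 had untreated signals of 4.08, 4.63, 3.88 and 5.79 in BCWM.1, against 9.08, 9.43, 7.60 and 10.73 in MWCL-1. In BCWM.1 CD180 fell as well (log2 -1.09, adjusted p = 0.00017, to a signal of 2.99) and GAPT did not pass (0.10, adjusted p = 0.709). Signals under the filter of 4.37, or close to it for IGHV3OR16-6, left little room there for falls as large as those in MWCL-1. The differences of CD180, GAPT and IGHV3OR16-6 thus do not show unequal responses.

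Among the lists, interferon response genes fell less in BCWM.1 (15 of 37 higher and 6 lower, median 0.24, but -0.77 when scaled to the poly-A controls, adjusted p = 6.79e-06 and adjusted p = 0.474 with an estimated correlation). IFI6 stood at 1.58, IFIT1 at 1.17 and MX1 at 0.75, but at 0.58 (adjusted p = 0.0912), 0.17 (0.598) and -0.25 (0.447) when so scaled, none of them called. MHC class II had 4 of 13 higher and 0 lower (median 0.18, but -0.82 when scaled to the poly-A controls, adjusted p = 0.000757 and adjusted p = 0.449 with an estimated correlation). HLA-DPB1 stood at 0.83. B-cell identity had 7 of 25 higher and 2 lower (median 0.17, but -0.83 so scaled, adjusted p = 0.00163 and adjusted p = 0.272 with an estimated correlation), and metallothioneins 5 of 9 higher and 1 lower (median 0.43, but -0.57 so scaled, adjusted p = 0.0114 and adjusted p = 0.272 with an estimated correlation). The interferon, B-cell identity and metallothionein lists were also called lower in untreated BCWM.1. Whether that level accounts for these differences was not tested. Lower responses in BCWM.1 were called for E2F targets (22 of 49, median -0.49, adjusted p = 1.37e-06 and adjusted p = 0.641 with an estimated correlation), mitosis (22 of 55, median -0.44, adjusted p = 6.4e-06 and adjusted p = 0.641 with an estimated correlation), MYC targets (11 of 39 with 1 higher, median -0.36, adjusted p = 0.00392 and adjusted p = 0.649 with an estimated correlation), histones (14 of 47, median -0.26, but 0.07 when centred on expressed coding genes, adjusted p = 0.00132 and adjusted p = 0.641 with an estimated correlation) and fatty acid synthesis (2 of 15, median -0.30, but 0.04 when so centred, adjusted p = 0.0431 and adjusted p = 0.641 with an estimated correlation). ELOVL6 stood at -1.64. The medians for E2F targets, mitosis, MYC targets, histones and fatty acid synthesis lay inside the central 95% of matched random lists, at percentiles 2.66, 17.9, 29.5, 62.1 and 35.3. The call of MYC targets ended with quantile normalization again (adjusted p = 0.0711), the stricter filter (0.0644) and centring on expressed coding genes (0.0630), and that of fatty acid synthesis with these (0.107, 0.0667 and 0.0657) and with the mean of a gene's probe sets (0.0571). The call of fatty acid synthesis also ended without BCWM.1 untreated replicate 1 (adjusted p = 0.0681) or 3 (0.0683), BCWM.1 NSC12 replicate 2 (0.127), MWCL-1 untreated replicate 1 (0.05003) or 3 (0.0636) or MWCL-1 NSC12 replicate 1 (0.0693). The other 21 lists did not pass as deposited, with adjusted p from 0.225 (hypoxia) to 0.962 (MYD88 and Toll-like receptor signalling, fibroblast and stromal markers), among them cholesterol synthesis (4 of 23 higher and 3 lower, adjusted p = 0.337) and LXR targets (0 of 9 higher and 3 lower, adjusted p = 0.386), whose members ABCA1 (-1.15), ABCG1 (-1.52) and LPCAT3 (-0.66) differed. The respiratory chain passed with quantile normalization again (adjusted p = 0.0341). Cholesterol synthesis had a median of 0.01 and a mean of -0.03, and MAPK feedback (-0.12), NF-kB (-0.08), the respiratory chain (-0.08), glycolysis (-0.04), JAK-STAT3 (-0.17) and chemokine receptors (-0.18) had negative medians with an upward camera direction. Adjusted over the list alone, the called lists counted 0 and 37 for the unfolded protein response, 1 and 34 for ATF4, 0 and 19 for NRF2, 0 and 25 for E2F targets, 0 and 24 for mitosis, 17 and 6 for interferon, 5 and 0 for MHC class II, 0 and 15 for histones, 8 and 2 for B-cell identity, 1 and 16 for MYC targets, 5 and 2 for metallothioneins and 0 and 4 for fatty acid synthesis.

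In this difference 4460 of 24204 genes passed, 781 higher and 3679 lower in BCWM.1, with 3335 and 1613 when centred on expressed coding genes and 45 and 20702 when scaled to the poly-A controls. Beside those of FGF2 and MYD88, centring on expressed coding genes ended the calls of SLC3A2 (-0.34, adjusted p = 0.110, the highest of a range from 3.74e-06), LPCAT3 (-0.33, 0.166, from 3.14e-05) and ERN1 (-0.41, 0.0835, from 1.35e-05), while FGFR1 (0.59, adjusted p = 0.0456) and MYC (0.45, 0.0425) passed. Leaving out 1 array ended the call of FGFR4 for BCWM.1 untreated replicates 2 (adjusted p = 0.0637) and 3 (0.0561), BCWM.1 NSC12 replicate 3 (0.0622) and MWCL-1 untreated replicates 1 (0.0544), 2 (0.0533) and 3 (0.0523), and that of FGF2 for BCWM.1 untreated replicate 2 (0.0527), BCWM.1 NSC12 replicate 2 (0.0502) and MWCL-1 NSC12 replicate 3 (0.0523). A replicate block ended both (0.0586 for FGFR4 and 0.0541 for FGF2).

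Averaged over both lines, MYD88 fell (log2 -1.85, SE 0.10, adjusted p = 8.41e-09), BTK fell 2.27-fold and MYC rose 1.81-fold, with 6 treated and 6 untreated arrays. Scaled to the poly-A controls, MYC stood at -0.45 in BCWM.1 and 0.44 in MWCL-1, so its averaged rise depended on the scaling. The cyclin CCNE2 fell 7.21-fold, FAM111B 7.13-fold and ACAT2 6.14-fold, while ATF3 rose 6.40-fold and MT1F 5.40-fold. In total 3521 genes were higher and 8531 lower, against 12278 and 4147 when centred on expressed coding genes and 344 and 22670 when scaled to the poly-A controls. By camera 7 of the 33 lists were higher and 11 lower, and 1 of these calls, that of the metallothioneins (median 1.66, adjusted p = 4.46e-10), held with an estimated correlation (adjusted p = 0.0204). The unfolded protein response was called higher (adjusted p = 0.0262, and adjusted p = 0.624 with an estimated correlation) with a median of -0.02 and a mean of 0.11, and the call ended without BCWM.1 NSC12 replicate 1 (adjusted p = 0.0679) or with no filter (0.0751).

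The lines, which had separate untreated controls, shared 1332 genes called up and 4071 called down, where independence would give 298 and 1700. These expected counts spread the calls evenly over all genes. Called falls of coding genes were commoner at brighter signals. Shares were 18.6% at mean signals of 5 to 6 and 77.1% at 10 to 11 in BCWM.1, and 8.92% and 52.6% in MWCL-1. The excess of shared falls thus does not by itself show a specific shared response. Of the rises, 1050 of 2972 in BCWM.1 and 1103 of 2428 in MWCL-1 were of coding genes. Many others were of small RNA families whose members share sequence, such as U6 (375 and 378). Their calls are not independent, so the excess of shared rises does not by itself show such a response either. The part of these families in the shared rises was not counted. Shared rises outnumbered shared falls when arrays were centred on expressed coding genes, but not when scaled to the poly-A controls. Of the MWCL-1 calls, 54.9% of the rises and 82.3% of the falls were also called in BCWM.1, and 39 rises and 274 falls of BCWM.1 were called the opposite way in MWCL-1. Across genes, Pearson's r of the log2 fold changes was 0.668 and Spearman's rho 0.620, and across expressed coding genes 0.632 and 0.645. JUN, ATF3, MT1F and DUSP4 were among the shared rises and CDK1, PCNA, ACAT2 and TLR10 among the shared falls.

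**Figure D4:**
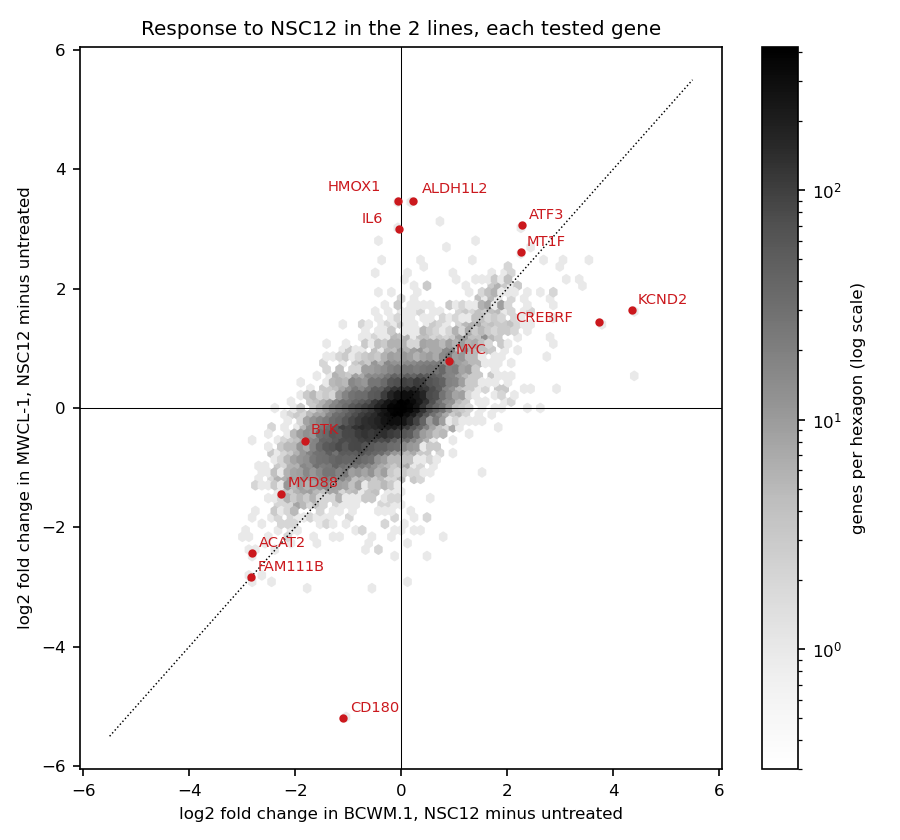
Log2 fold change after NSC12 in BCWM.1 (horizontal) and MWCL-1 (vertical) for 24204 tested genes, with grey hexagons shaded on a log scale by the number of genes, a dotted line of equal change and 13 named genes in red. ATF3 and MT1F rose in both lines, HMOX1, ALDH1L2 and IL6 rose in MWCL-1 and had log2 values of -0.06, 0.23 and -0.03 in BCWM.1, and CD180 stood at -5.20 in MWCL-1, where its treated signal was near background.

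The untreated lines were compared to give the baseline of these responses. CD96, an immunoglobulin-family receptor, was 129-fold lower in BCWM.1 than in MWCL-1 (log2 -7.01, SE 0.11, n = 3 arrays per group, adjusted p = 9.88e-14), and the transcription factor BCL11A (62.5-fold), the B-cell scaffold BANK1 (53.7-fold) and the kappa segment IGKV1-17 (110-fold) were lower as well. UGT2B17 (78.2-fold) and UGT2B15 (75.2-fold), which glucuronidate steroids, PRKACB (60.8-fold), CPM (60.4-fold), STEAP2 (54.2-fold) and TDO2 (53.5-fold) completed the 10 largest of this direction. Higher in BCWM.1 were the chemokine CCL20 (103-fold, log2 6.68, SE 0.17, adjusted p = 6.6e-12), EPB41L4A (70.5-fold), SCML1 (51.6-fold), the ceramide synthase CERS6 (48.6-fold), GNAQ (48.4-fold), UGGT2 (43.5-fold), AUTS2 (39.6-fold), SERPINB10 (39.5-fold), C1orf21 (37.5-fold) and NID1 (35.2-fold). All of these genes but IGKV1-17, UGT2B17, CERS6, AUTS2 and SERPINB10 had a signal under the filter for dim genes in the line with the lower level, so that background limits their folds. JCHAIN was 15.8-fold and the lambda constant gene IGLC3 25.1-fold higher in BCWM.1.

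No difference in MYD88 between the untreated lines was called (log2 -0.27, adjusted p = 0.211). FGF2 was 4.26-fold lower in BCWM.1 (log2 -2.09, SE 0.13, adjusted p = 5.46e-08), FGFR1 2.16-fold lower (log2 -1.11), FGFR4 1.56-fold lower (-0.64) and BTK 1.70-fold lower (-0.76), and FGFR2 (0.06) did not pass. Both FGFR2 and FGFR3 were dim and were removed by the stricter filter. FGFR3 was lower (-0.64, adjusted p = 0.0169), a call that ended without BCWM.1 untreated replicate 1 (-0.58, adjusted p = 0.0611) or MWCL-1 untreated replicate 2 (-0.58, 0.0667), and MYC was higher (0.36, adjusted p = 0.0253), a call that ended without BCWM.1 untreated replicate 2 (0.36, 0.0589) or 3 (0.35, 0.0813) or MWCL-1 untreated replicate 1 (0.38, 0.0547), 2 (0.38, 0.0614) or 3 (0.33, 0.0962).

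By list, 29 of 37 interferon response genes were lower and 1 higher in BCWM.1 (median -0.75, adjusted p = 7.26e-15 and adjusted p = 0.131 with an estimated correlation). IFIT1 stood at -2.19, GBP1 at -1.29 and IFI6 at -1.16. B-cell identity had 16 of 25 lower and 4 higher (median -0.74, adjusted p = 3.65e-07 and adjusted p = 0.0827 with an estimated correlation). STAP1 stood at -2.52. Metallothioneins had 7 of 9 lower (median -0.93, adjusted p = 4.1e-07 and adjusted p = 0.0646 with an estimated correlation). MT1F stood at -1.65. B-cell receptor signalling had 11 of 26 lower and 3 higher (median -0.33, adjusted p = 0.00487 and adjusted p = 0.322 with an estimated correlation). SYK stood at -2.32. MYC targets had 22 of 39 higher (median 0.46, adjusted p = 1.17e-12 and adjusted p = 0.142 with an estimated correlation). The ATF4 list had 20 of 43 higher and 2 lower (median 0.36, adjusted p = 1.29e-08 and adjusted p = 0.186 with an estimated correlation), and SLC7A11 stood at 1.85. Higher levels were also called for E2F targets (21 of 49, median 0.34, adjusted p = 2.79e-07 and adjusted p = 0.376 with an estimated correlation), heat shock (13 of 21, median 0.48, adjusted p = 4.43e-07 and adjusted p = 0.142 with an estimated correlation) and p53 targets (16 of 30 with 1 lower, median 0.37, adjusted p = 1.75e-06 and adjusted p = 0.131 with an estimated correlation).

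Further shifts between the untreated lines were called upward for NF-kB (12 of 28 higher and 3 lower, adjusted p = 0.00012 and adjusted p = 0.275 with an estimated correlation), glycolysis (8 of 20 higher, adjusted p = 0.000238 and adjusted p = 0.275 with an estimated correlation), hypoxia (9 of 23 higher and 1 lower, adjusted p = 0.000402 and adjusted p = 0.328 with an estimated correlation), NRF2 (10 of 28 higher and 3 lower, adjusted p = 0.012 and adjusted p = 0.328 with an estimated correlation), cholesterol synthesis (6 of 23 higher and 4 lower, adjusted p = 0.0185 and adjusted p = 0.43 with an estimated correlation) and IgM and immunoglobulin constant genes (3 of 8 higher and 1 lower, median 0.19 and mean 1.33, adjusted p = 0.0185 and adjusted p = 0.245 with an estimated correlation). They were called downward for autophagy and lysosome (18 of 48 lower and 1 higher, adjusted p = 0.000161 and adjusted p = 0.385 with an estimated correlation), histones (14 of 47 lower, adjusted p = 0.000389 and adjusted p = 0.385 with an estimated correlation) and the respiratory chain (17 of 50 lower and 4 higher, adjusted p = 0.0185 and adjusted p = 0.653 with an estimated correlation). Scaling to the poly-A controls ended the calls of cholesterol synthesis (adjusted p = 0.121) and the respiratory chain (0.161), and centring on expressed coding genes that of IgM and immunoglobulin constant genes (0.0537). The other 15 lists did not pass, with adjusted p from 0.0707 (fatty acid synthesis) to 0.968 (JAK-STAT3, MAPK feedback, chemokine receptors). MYD88 and Toll-like receptor signalling passed without BCWM.1 untreated replicate 3 (adjusted p = 0.0401) or with no filter (0.0342). Fatty acid synthesis passed without MWCL-1 untreated replicate 2 (0.0460), with the stricter filter (0.0342) or with scaling to the poly-A controls (0.0431). By fry these passed too (0.00168 and 0.00135), as did MHC class II (0.00777), plasma cell (0.0011) and FGF genes (0.00168). JAK-STAT3 signalling had a median of 0.10, a mean of -0.12 and a downward camera direction, and chemokine receptors a median of -0.13 with an upward direction. Adjusted over the list alone, the called lists with other counts were interferon (1 and 32), MYC targets (31 and 0), ATF4 (22 and 5), E2F targets (26 and 1), heat shock (14 and 0), NF-kB (13 and 3), autophagy (2 and 23), glycolysis (11 and 0), hypoxia (10 and 2), B-cell receptor (3 and 12), NRF2 (10 and 4), cholesterol synthesis (10 and 4) and the respiratory chain (4 and 20). Between the untreated lines 2333 genes were higher and 3376 lower in BCWM.1, against 3500 and 2602 when centred on expressed coding genes and 958 and 2333 when scaled to the poly-A controls.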

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

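The tests of mRNA amount, signal compression, LXR targets and cycling cells were chosen only after the results they concern were seen.

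The median signal of the expressed coding genes on an array fell with NSC12 by 0.56 in BCWM.1 and 0.23 in MWCL-1. The median change over these genes was -0.46 and -0.17. At the same time several control probe sets that no comparison used went up. The poly-A controls, which enter before labelling, rose by 1.36 in BCWM.1 and 0.36 in MWCL-1, the hybridization controls, which enter after it, by 0.23 in BCWM.1 and 0.29 (ranges overlapping) in MWCL-1, and background probes of high GC content by 0.18 and 0.36, whereas those of low GC content moved by -0.12 and 0.04. Compression of bright signals was argued against as the whole cause in BCWM.1, since the bright bioD and cre controls moved by 0.16 (SE 0.08) and not downward, but the rise shrank with brightness (bioB 0.33, bioC 0.28, bioD 0.21, cre 0.12), so a part of it stays open. A smaller amount of cellular mRNA beside the added controls may explain the BCWM.1 fall, since the poly-A controls rose 1.13 (SE 0.16) more than the hybridization controls, with no overlap of treated and untreated arrays (exact permutation p = 0.1, the smallest possible). In MWCL-1 that rise was 0.065 (SE 0.13, with an upper bound of 0.33 above the fall of 0.23), so this explanation cannot be told apart from none there, and whether a lower mRNA content or a different addition of controls is the source was not tested.

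The responses of the lines differed for 4460 genes by the test of the difference. Of these patterns, the stress response was weighed: the ATF4 list differed by a median of -0.77 and the unfolded protein response by -1.19, calls that did not hold with an estimated correlation (adjusted p = 0.123 for each). A larger general fall of coding genes in BCWM.1 was argued against for both, because each median lay at percentile 0 of random coding lists of matched expression. A higher untreated level in BCWM.1 may explain the ATF4 difference: after centring on expressed coding genes the list lay 0.60 (SE 0.04) higher in untreated BCWM.1, and the treated lines differed by 0.039 (SE 0.028). It was argued against for the unfolded protein response, which lay 0.19 (SE 0.02) higher in untreated BCWM.1 and -0.60 (SE 0.02) lower after treatment, so that a difference between the lines in this response stays open as a hypothesis.

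Cholesterol synthesis genes fell in both lines, with medians of -1.26 in BCWM.1 and -1.22 in MWCL-1 as deposited but -2.62 and -1.58 when scaled to the poly-A controls. A general fall of coding genes was argued against, since the list lay at percentile 0 of the matched random lists in BCWM.1 and at percentile 0 in MWCL-1. A response like that to added sterol, with LXR activation, could not be decided: ABCA1 and ABCG1 rose as deposited (but -0.37 and -0.83 in BCWM.1 when so scaled) while LPCAT3 fell, and the LXR list had a camera adjusted p of 0.135 in the average response, though 0.0382 when so scaled and 0.00203 by fry, and no call in BCWM.1 in any of these. Fewer cycling cells, with lipid genes falling beside cell-cycle genes, likewise stayed open and could contribute. The cholesterol list differed from the fatty acid list by -0.25 in BCWM.1, with bounds of this difference at -0.92 and 0.21. In MWCL-1 the difference was -0.71, with bounds at -1.44 and -0.08. The bounds in both lines came from resampling the genes of the lists, not the arrays. Genes of a list are not independent, so these bounds do not show that the cholesterol list fell more in MWCL-1. Comparing these lists does not measure the share of cycling cells, so it cannot decide this explanation.

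The other lists whose response differed between the lines by camera had median differences of -0.58 (NRF2), -0.49 (E2F targets), -0.44 (mitosis), -0.36 (MYC targets), -0.30 (fatty acid synthesis), -0.26 (histones), 0.17 (B-cell identity), 0.18 (MHC class II), 0.24 (interferon) and 0.43 (metallothioneins). None of these calls held with an estimated correlation (adjusted p from 0.123 to 0.649), the 4 positive medians were negative when scaled to the poly-A controls, and those of fatty acid synthesis and histones were positive when centred on expressed coding genes. Interferon, B-cell identity and metallothionein genes also stood lower in untreated BCWM.1, and whether this accounts for their differences was not tested. Genes with a smaller rise or larger fall in BCWM.1 were HMOX1 (-3.53), ALDH1L2 (-3.23), RGCC (-3.18), IL6 (-3.03), IL1A (-2.81), TRIB3 (-1.92), SLC7A11 (-1.67), ELOVL6 (-1.64), ABCG1 (-1.52), CTH (-1.43), PDIA6 (-1.36), BTK (-1.28), SEC24D (-1.19), ABCA1 (-1.15), MYD88 (-0.83), ERN1 (-0.74), FGF2 (-0.71), SLC3A2 (-0.68) and LPCAT3 (-0.66). Those with the opposite difference were FGFR4 (0.60), MX1 (0.75), HLA-DPB1 (0.83), IFIT1 (1.17), IFI6 (1.58), IGKV1D-39 (2.94), GAPT (3.04), IGHV3OR16-6 (3.05), MIR8061 (3.94) and CD180 (4.11). Untreated signals of CD180, GAPT and IGHV3OR16-6 in BCWM.1 lay under or close to the filter for dim genes, which left little room for falls there.

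With the arrays split in other ways, 1 of 100 splits, the real one, called as many genes for the average response (12052, highest other 7294). Chance in the assignment of these arrays was thus unlikely for it but not excluded, since 1 of 100 is the smallest share possible. Chance between cultures stays open if the arrays of a group share 1 culture. For the difference between the lines the real split was also 1 of 100 (4460, highest other 3093). These splits add the treatment effect to the spread and do not hold the responses equal, so they decide nothing there. For BCWM.1 (11293, highest other 0), MWCL-1 (7372, highest other 0) and the untreated lines (5709, highest other 0), the real split was 1 of 10, and 10 splits are too few for a share under 0.05. The groups hold 3 arrays each, so single arrays were not tested for lying apart.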

How the results depend on the processing

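Centring on expressed coding genes and scaling to the poly-A controls were chosen only after the data were seen. All 18 counts stayed within 1.5 times their value, and no reported gene or list reversed, under median centring, quantile normalization again, no filter, the stricter filter, the mean of probe sets, the trended prior, array weights, the replicate block and single arrays left out. The replicate numbers did not pair the arrays (same-number r from -0.175 to 0.041); with a replicate block 2743 genes rose and 7948 fell in BCWM.1, 2106 and 4302 in MWCL-1, and 7 of 255 gene values lost their call, those of FGFR4 and FGF2 in BCWM.1 and in the difference, SEC24D in BCWM.1 and FGF8 and IL6ST in MWCL-1. With 1 array left out, 36 of 1728 gene values lost a call and 4 gained one, and rises and falls ranged over 2551 to 2853 and 7509 to 8307 in BCWM.1 and 1939 to 2101 and 3938 to 4389 in MWCL-1. List calls were less stable: 9 of 165 were lost with quantile normalization again, 7 with the stricter filter and 78 with an estimated correlation. Signals near the filter limit the size of falls in dim genes such as CD180 in BCWM.1. Where a value below changed, the cause was not tested, except that all probes and stricter limits alter the number of tests or the limit itself.

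With all probes, 9277 probe sets rose in BCWM.1, 4257 in MWCL-1, 10506 in the average and 2088 in the difference, and 2108 rose in both lines. The correlation of fold changes across these probe sets was 0.548. They include probe sets without a gene symbol and several of the same gene, so these are not values over genes. With a 2-fold limit, 653 rose and 3048 fell in BCWM.1, 571 and 885 in MWCL-1, 491 and 1511 in the average, 242 and 1242 in the difference, 612 and 985 differed between untreated lines, and 342 and 643 were shared. At adjusted p under 0.01, 1943 rose in BCWM.1, 1532 in MWCL-1 and 855 in both, 296 were higher and 1903 lower in the difference, and 1478 and 2233 between untreated lines.

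For camera with an estimated correlation, 1 list was called in BCWM.1, 4 in MWCL-1, 1 in the average, 0 in the difference and 0 between untreated lines. List calls also ended under other alternatives. With quantile normalization again these were, in BCWM.1, B-cell receptor signalling (adjusted p = 0.166), interferon (0.0716), NRF2 (0.244), FGF (0.0505) and the unfolded protein response (0.363), B-cell receptor signalling in MWCL-1 (0.107) and the average (0.0987), and fatty acid synthesis (0.107) and MYC targets (0.0711) in the difference. With the stricter filter these were B-cell receptor signalling (0.096), interferon (0.096), NRF2 (0.223) and the unfolded protein response (0.223) in BCWM.1, B-cell receptor signalling in MWCL-1 (0.051), and fatty acid synthesis (0.0667) and MYC targets (0.0644) in the difference. With no filter the NRF2 list in MWCL-1 (0.0514) and the unfolded protein response in the average (0.0751) lost their calls. By fry, 28 were called in BCWM.1, 30 in the average and 19 in the difference. By fry, lists for autophagy, chemokine receptors, fibroblasts, heat shock, hypoxia, immunoglobulin constant genes, MHC class II, p53 and plasma cells gained a call in BCWM.1 and FGF lost it (adjusted p = 0.0531). In the difference the gains were autophagy, B-cell receptor signalling, heat shock, hypoxia, LXR targets, p53 and plasma cells. Fry gave a downward direction where camera had an upward one for B-cell identity (adjusted p = 0.00555), the BCL2 family (0.0406) and MYD88 and Toll-like receptor signalling (0.00103) in BCWM.1, and for the BCL2 family (0.0220) and MYD88 and Toll-like receptor signalling (0.000934) in the average. The highest adjusted p of these results over the alternatives were 0.962, 0.951, 0.968, 0.995 and 0.994, and the fry values were the lowest.

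Centred on expressed coding genes, rises and falls numbered 12349 and 3843 in BCWM.1, 5235 and 2932 in MWCL-1, 12278 and 4147 in the average, 3335 and 1613 in the difference and 4252 and 1910 in both lines, and 3500 were higher in untreated BCWM.1. In BCWM.1 FGF2 (0.17), HMOX1 (0.50), IFI6 (0.023) and HLA-DPB1 (0.18) reversed, and FGFR1, FGFR2, ALDH1L2, GAPT, SLC7A11 and IGHV3OR16-6 became called rises. In MWCL-1 FGF2, PIM1 and MIR8061 became called rises and TFB2M lost its call, as did FGFR3 between the untreated lines. Calls ended for the unfolded protein response list in BCWM.1 (adjusted p = 0.0588), fatty acid synthesis (0.0657) and MYC targets (0.0630) in the difference and immunoglobulin constant genes between untreated lines (0.0537).

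Scaled to the poly-A controls, rises and falls numbered 128 and 23384 in BCWM.1, 675 and 8643 in MWCL-1, 344 and 22670 in the average, 45 and 20702 in the difference and 103 and 8624 in both lines, and 958 were higher in untreated BCWM.1. In BCWM.1 these reversed: FGFR1 (-1.13), FGFR2 (-1.20), FGFR4 (-1.05), MYC (-0.45), ALDH1L2 (-1.13), TRIB3 (-0.54), GAPT (-1.26), NFKBIA (-0.069), TNFAIP3 (-0.48), REL (-0.58), SLC3A2 (-0.12), ABCA1 (-0.37), ABCG1 (-0.83), FGF8 (-0.87), FGF9 (-0.83), SQSTM1 (-0.68), SEC24D (-0.94), ERN1 (-0.73), SLC7A11 (-1.14), IGHV3OR16-6 (-0.84), IGKV1D-39 (-0.54) and PMAIP1 (-0.53). In the difference FGFR1 (-0.75), FGFR4 (-0.40), MYC (-0.88), MX1 (-0.25) and HLA-DPB1 (-0.17) reversed. Calls were lost by CTH, DNAJB9, IRAK2 and BCL2L11 in BCWM.1, by MYC, NFKBIA, TNFAIP3, REL, FGF8, IL6ST, BCL2L11 and PMAIP1 in MWCL-1, by IFIT1 and IFI6 in the difference and by MYC between the untreated lines. Falls became called for FGFR3, HMOX1, IL6, RGCC and IL1A in BCWM.1 and FGFR4 and PDIA6 in MWCL-1, as did the differences of FGFR2 and FGFR3. List calls ended for FGF (adjusted p = 0.0917) and the unfolded protein response (0.0917) in BCWM.1, B-cell receptor signalling (0.0518) and histones (0.0521) in MWCL-1, FGF in the average (0.112), and cholesterol synthesis (0.121) and the respiratory chain (0.161) between untreated lines, and LXR targets became called in MWCL-1 (0.0236) and the average (0.0382).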

Other observations

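Several families of small RNA genes, chosen after their values were seen, had more called rises than falls as deposited. Of 532 tested genes of the U6 family, 375 rose in BCWM.1 (median 0.82, but -0.54 when scaled to the poly-A controls) and 378 in MWCL-1 (median 0.82). The U1 family had 74 of 87 higher in BCWM.1 (median 1.10, but -0.26 so scaled) and 69 in MWCL-1 (0.91). H/ACA snoRNAs had 54 of 68 higher in BCWM.1 (median 0.91, but -0.45 so scaled) and 52 in MWCL-1 (0.88), and C/D snoRNAs 50 of 78 in BCWM.1 (0.63, but -0.73 so scaled) and 36 in MWCL-1 (0.42). Small Cajal body RNAs had 16 of 20 higher in BCWM.1 (median 0.97, but -0.39 so scaled) and 13 in MWCL-1 (0.78). The 5S family had 189 of 310 higher in BCWM.1 (median 0.58, but -0.78 so scaled) and 138 in MWCL-1 (0.41). In MWCL-1 no median of these 6 families flipped under any scaling. The 7SK family changed less, with 51 of 167 higher in BCWM.1 (median 0.25, but -1.11 so scaled) and 9 in MWCL-1 (0.08, but -0.27 so scaled). The 7SL family had 249 of 530 higher in BCWM.1 (median 0.35, but 513 lower so scaled) and 148 in MWCL-1 (0.26, but -0.10 so scaled). Members of such multigene families share sequence, so that their probe sets are not independent. The families were taken by the start of the gene symbol, without separating pseudogenes, so these are not counts of separately changed genes.

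Kappa variable segments, also chosen after their values were seen, fell in MWCL-1, with 29 of 70 tested genes lower and 0 higher (median -0.36). In BCWM.1 1 rose and 0 fell (median 0.01, but -0.04 when arrays were centred on their median, with 53 higher when centred on expressed coding genes and 70 lower when scaled to the poly-A controls). The difference between the lines passed for 26 of them (median 0.44, but -0.57 when scaled to the poly-A controls). Of these 26, 25 had a lower untreated signal in BCWM.1 (median 5.80 against 7.88), 1 lay under the filter for dim genes there and 14 lay under the 75th percentile of all values (5.89). The lower level left less room for falls in BCWM.1, and whether it accounts for the difference was not tested. Kappa segments also share sequence, so that their probe sets are not independent.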
